A study of Dorcoceras hygrometricum with 3 samples.

How the data were processed

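Genomic DNA came from leaves of potted Boea hygrometrica plants that were hydrated, dehydrated to 70% relative water content or desiccated to 10% relative water content, with 1 library per condition and 3 libraries in all. Per the labels' protocols, the DNA was sonicated, ligated to methylated adaptors, treated with bisulfite by a commercial kit, size selected and amplified by PCR before sequencing. Bisulfite converts unmethylated cytosines, so the methylation level of a stretch is the fraction of its cytosine calls that stayed unconverted. The aligner, the caller of differential regions, the sequence contexts used, the conversion rate and the genome build are not given in the sources used here.

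The deposited methylation level of a region is a fraction from 0 to 1 with 2 decimals, per the file headers a mean for the hydrated library and one for the dehydrated library. Other deposited columns hold region length in bp, gene positions, Gene Ontology terms, KEGG descriptions, the part of the gene and the direction assigned by the authors. There were 3660 genes in the 10% RWC file and 3177 genes in the 70% RWC file, each once, followed by 54694 and 57411 blank lines that were left out. In every case the assigned direction matched the sign of the difference and the stated length matched the coordinates. Gene ends were rounded by a spreadsheet for 255 and 108 genes, so gene ends were taken as start plus length. The values show how regions had been selected before deposit. The higher of the 2 levels was at least 0.1 and the ratio of levels was at least 1.86, which with 2 decimals is compatible with a doubling, and regions were at least 201 bp long. Regions assigned to a flank lay within 1887 bp of their gene.

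A region listed for several genes was counted once where regions were counted, giving 2690 regions at 70% RWC and 3093 at 10% RWC, and once per gene where genes, gene parts or functional lists were counted. Shares carry exact 95% binomial (Clopper-Pearson) intervals, and differences of shares carry normal intervals. Directions were compared between lists, gene parts and functional lists with two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over the tests of a family. The gene body effect was compared between lists by the interaction term of a logistic model over genes in 1 list only. Overlaps were found with bedtools 2.31.1, at 1 bp or more, at a reciprocal 50%, or with identical boundaries. The 10 functional lists were drawn by keyword from the descriptions and Gene Ontology terms, and 32 of 159 memberships at 70% RWC and 34 of 170 at 10% RWC rest on a term alone, among them 14 of the 25 and 14 of the 21 photosynthesis genes. A list's median was ranked among 10000 random lists of its size matched on mean level. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 were used.

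The rule for named genes was set before the data were examined. Names come from the 5 largest absolute differences per comparison and direction, the 5 largest shared changes of the same and of opposite direction, and members of the functional lists among the 20 largest differences per comparison. The argonaute gene meets the rule at 70% RWC. Of the genes under this rule, list members that entered by a Gene Ontology term with an unrelated description or none are counted and not named, and some of the largest differences at genes without a description are left out for brevity.

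Tests were first tried on simulated data. At 10% RWC, lists of 20 genes had 95% of their genes set to increase, with the majority. The direction test recovered 97.5% of these planted lists among 3660 genes and called 4.5% of unchanged lists. At 70% RWC, 95% of the planted genes were set to decrease, against the majority. Among 3177 genes, 100% of planted lists were recovered and 0% of unchanged lists called, or 2.5% where 99% were set to decrease. Lists set to increase at 70% RWC, lists of fewer than 20 genes, and leans weaker than 95% were not tried. Each trial held as many planted as unchanged lists. How often moderate leans would be recovered is therefore unknown. A planted odds ratio of 2 was recovered as 1.77 (1.54 to 2.04) at 10% RWC and 2.06 (1.77 to 2.38) at 70% RWC. The shared hydrated library was simulated with unchanged dehydrated libraries at 20, 50 and 100 assumed calls per region. Noise alone was simulated with 10 or 20 assumed calls at the median length, in proportion to length, and a dehydrated library 2 or 4 times deeper.

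Alternatives tried were a minimum difference of 0.2, 0.3 or 0.5, weighting by length, merging of same-direction regions within 100 bp, 1 region per scaffold, other overlap rules, a minimum move of 0.1 and log2 ratios with 0.01 added. Counting genes, leaving out regions that overlap the other list, keeping regions listed for 1 gene, drawing functional lists from descriptions alone, and comparing within bins of level were added after the data had been seen. Since coverage, cytosine numbers, read counts, p-values and contexts are not in the tables, no test per region, filter on coverage or split by context was made.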

Results

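Leaf DNA methylation was measured by whole-genome bisulfite sequencing in Boea hygrometrica, a resurrection plant whose leaves survive the loss of nearly all their water and recover when watered again. Leaves came from 3 conditions of potted plants: hydrated, dehydrated to 70% relative water content (RWC), and desiccated to 10% RWC. Each condition was represented by 1 library, so every difference below is between single libraries, has no replicate check, and cannot be separated from differences between plants or library preparations. The deposited tables list gene-associated regions whose methylation level, a fraction from 0 to 1, differed between the hydrated library and 1 dehydrated library. They give no read counts and no coverage, so the depth behind each level is unknown and no interval is given for a single level. Intervals on shares of regions or genes are exact 95% binomial intervals that cover counting only. P-values over regions or genes describe these libraries, since regions and genes are not replicates. Sequence context (CG, CHG or CHH) and strand are not in the tables, and the genome build is not given in the sources used here; positions are the scaffold coordinates of the deposited tables.

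The first comparison asks where leaf methylation differed after moderate water loss. At 70% RWC most listed regions were more methylated than in the hydrated leaf, and this held in gene bodies and on both sides of genes. The list held 2690 distinct regions assigned to 3177 genes. The level was higher at 70% RWC in 1893 regions and lower in 797, an increased share of 70.4% (68.6 to 72.1). Counted by gene, 2243 genes carried a region of higher level and 934 a region of lower level. Among the increased regions the median level was 0.14 in the hydrated leaf and 0.36 at 70% RWC, and the median difference was 0.22 (quartiles 0.16 and 0.29). Among the decreased regions the medians were 0.36 and 0.13, with a median difference of -0.21. On a log2 scale, with 0.01 added to each level, the median differences were 1.25 and -1.27.

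The largest increases at 70% RWC lay beside or within genes without a functional description. A stretch of 440 bp downstream of Bhs3890_002V1.1 (scaffold3890, 25397 to 25836) was listed at 0 in the hydrated leaf and at 1 at 70% RWC. Downstream of Bhs9669_003V1.1 (scaffold9669, 22000 to 22334) the level was 0 and then 0.97. The next largest increases were upstream of Bhs12746_001V1.1, from 0.14 to 1, and in the bodies of Bhs12233_001V1.1, from 0.20 to 1, and Bhs2051_001V1.1, from 0.18 to 0.98. The largest decreases were in the body of Bhs1761_010V1.1 (scaffold1761, 283410 to 283612), where the level was 1 in the hydrated leaf and 0.25 at 70% RWC, and upstream of Bhs2524_019V1.1, where it was 1 and 0.32. Upstream of Bhs10451_001V1.1, described as a C4-hydroxylase, the level was 0.89 and 0.28. How many reads stand behind levels of exactly 0 or 1 is unknown.

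Among the largest differences at genes of known function at 70% RWC, genes of the cell wall and of protein folding went both ways. Gains at a light-harvesting gene and a photosystem II gene were also among them. The largest differences also included a gain (0.33 and 0.71) and a loss (0.57 and 0.13) at photosynthesis list members without a description. Of all listed genes 70.6% were higher, against 88.0% of the photosynthesis, 71.4% of the cell wall and 62.9% of the chaperone genes. None of these lists differed from the other listed genes after correction. A region in the body of Bhs6817_001V1.1 had a level of 0.21 in the hydrated leaf and 0.91 at 70% RWC. This gene encodes a chlorophyll a/b binding protein of light-harvesting complex I, the antenna of photosystem I. Downstream of Bhs8788_004V1.1, which encodes PsbY, a small subunit of photosystem II, the levels were 0.03 and 0.39. Upstream of Bhs2524_006V1.1, a xyloglucan:xyloglucosyl transferase, an enzyme that cuts and rejoins wall xyloglucan, the level was 0 and 0.60. Downstream of the pectinesterase gene Bhs8446_001V1.1 it was 0 and 0.50. Upstream of the DnaJ chaperone gene Bhs422_001V1.1 it was 0.05 and 0.55. Both named peroxidase genes had higher levels, Bhs1834_003V1.1 in its body (0.31 and 0.68) and Bhs12_006V1.1 upstream (0.06 and 0.43). Lower levels were listed upstream of Bhs18_073V1.1, an endoribonuclease Dicer, which makes small RNAs that can guide DNA methylation (0.53 and 0.08). Upstream of Bhs1073_015V1.1, a xanthoxin dehydrogenase of abscisic acid synthesis, the level was 0.83 in the hydrated leaf and 0.39 at 70% RWC. A 70 kDa heat shock protein gene, Bhs7881_001V1.1, and a cellulose synthase gene, Bhs710_021V1.1, both went from 0.78 to 0.37, in the body and downstream respectively. Genes of the ethylene-responsive factor family went both ways, with 0.25 and 0.65 downstream of Bhs3150_003V1.1 and 0.40 and 0.02 upstream of Bhs6670_003V1.1.

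The second comparison asks where methylation differed in the desiccated leaf. At 10% RWC gains and losses were closer to balance, and the typical loss was larger than the typical gain as a difference of levels, though smaller as a log2 ratio. The list held 3093 distinct regions assigned to 3660 genes. The level was higher at 10% RWC in 1729 regions and lower in 1364, an increased share of 55.9% (54.1 to 57.7). By gene, 2041 had a region of higher level and 1619 a region of lower level. The increased regions had median levels of 0.10 in the hydrated leaf and 0.28 at 10% RWC, a median difference of 0.18 (quartiles 0.13 and 0.26). The decreased regions had medians of 0.40 and 0.16, a median difference of -0.24 (quartiles -0.32 and -0.16). The log2 medians were 1.33 and -1.19. The majority changed sides with the size of the difference: among regions that differed by at least 0.2, 750 were higher and 884 lower, and at 0.3 or more 299 were higher and 432 lower. The 83 regions that differed by at least 0.5 were nearly even, with 43 higher and 40 lower.

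The most altered regions at 10% RWC again lay at genes without a description. Downstream of Bhs2033_017V1.1 (scaffold2033, 187601 to 187819) the listed level was 0 in the hydrated leaf and 1 at 10% RWC. The region downstream of Bhs9669_003V1.1 that had gained most of its methylation at 70% RWC was listed here too, at 0 and 0.95. Upstream of Bhs2002_010V1.1 and Bhs3527_001V1.1 the level at 10% RWC was 1, against 0.17 and 0.18 in the hydrated leaf. Downstream of Bhs200_093V1.1 and upstream of Bhs422_025V1.1 the level was 0.88 in the hydrated leaf and listed at 0 at 10% RWC. In the body of Bhs9095_001V1.1 it was 1 and 0.25.

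Named genes at 10% RWC had both losses and gains, with losses at several transcription factor genes. Downstream of Bhs730_002V1.1, an MYB transcription factor of plants, the level was 0.74 in the hydrated leaf and 0.06 at 10% RWC. A second MYB gene, Bhs3283_020V1.1, had 0.80 and 0.38 downstream. Lower levels were also listed at the ethylene-responsive factor genes Bhs685_042V1.1 (0.68 and 0.28, upstream) and Bhs1878_003V1.1 (0.75 and 0.37, downstream). Upstream of Bhs1494_002V1.1 the level was 0.84 in the hydrated leaf and 0.41 at 10% RWC (scaffold1494, 102495 to 102845). This gene encodes 9-cis-epoxycarotenoid dioxygenase, the enzyme of the rate-limiting cleavage in the synthesis of abscisic acid, the main hormone of water deficit. Genes of glutathione, the thiol that buffers oxidative stress, went both ways. Counted after their values were seen, 8 of 13 glutathione S-transferase, glutamate-cysteine ligase and glutathione peroxidase genes were higher at 10% RWC and 5 lower. At 70% RWC 9 of 10 were higher, some of them listed for the same region. A glutathione synthase gene, higher at 70% RWC, was not among those counted. Of all listed genes, 55.8% were higher at 10% RWC and 70.6% at 70% RWC. The 3 glutathione genes with the largest differences at 10% RWC had losses upstream. They were the glutathione S-transferase genes Bhs1945_007V1.1 (0.74 and 0.33) and Bhs1067_009V1.1 (0.52 and 0.17) and the glutamate-cysteine ligase gene Bhs211_054V1.1 (0.57 and 0.23). At 70% RWC Bhs211_054V1.1 was listed for a gain at another region, in its body (0.18 and 0.39). Losses were also listed downstream of the HtpG chaperone gene Bhs129_013V1.1 (0.45 and 0.06) and in the body of the pectinesterase gene Bhs983_005V1.1 (0.70 and 0.34), and upstream of Bhs1036_009V1.1, a galacturonosyltransferase of pectin synthesis (0.60 and 0.26). Gains were listed in the body of Bhs4909_003V1.1, a trehalose-phosphate synthase (0.11 and 0.45), and downstream of Bhs129_014V1.1, a DnaJ homolog (0.16 and 0.61), and of Bhs119_054V1.1, a second xyloglucan:xyloglucosyl transferase (0 and 0.38).

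Set side by side, the lists differed most at strongly methylated regions. The increased share was 14.5 percentage points higher at 70% than at 10% RWC (12.0 to 16.9; two-sided Fisher exact test over regions, odds ratio 1.87, p 4.86e-30), and 17.8 points higher (14.9 to 20.6) over regions that overlapped none of the other list. Regions were grouped by the higher of their 2 levels. In the lowest group, from 0.1 to below 0.2, the increased share was 64.9% at 70% RWC and 71.7% at 10% RWC. In the highest, 0.5 and above, it was 67.7% and 38.7%. From the lowest to the highest group the share fell by 33.0 points at 10% RWC (28.2 to 37.9), and at 70% RWC the same difference was -2.81 points (-8.27 to 2.65). Desiccated leaves had mostly gains among weakly methylated regions and mostly losses among strongly methylated ones, while leaves at 70% RWC had mostly gains at every level. Depth is unknown, and simulated unchanged libraries with 10 and 20 assumed calls in the hydrated library also gave a fall, of 14.1 and 20.7 points with a dehydrated library 2 times deeper and of 34.8 points in either case with one 4 times deeper.

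**Figure D1:**
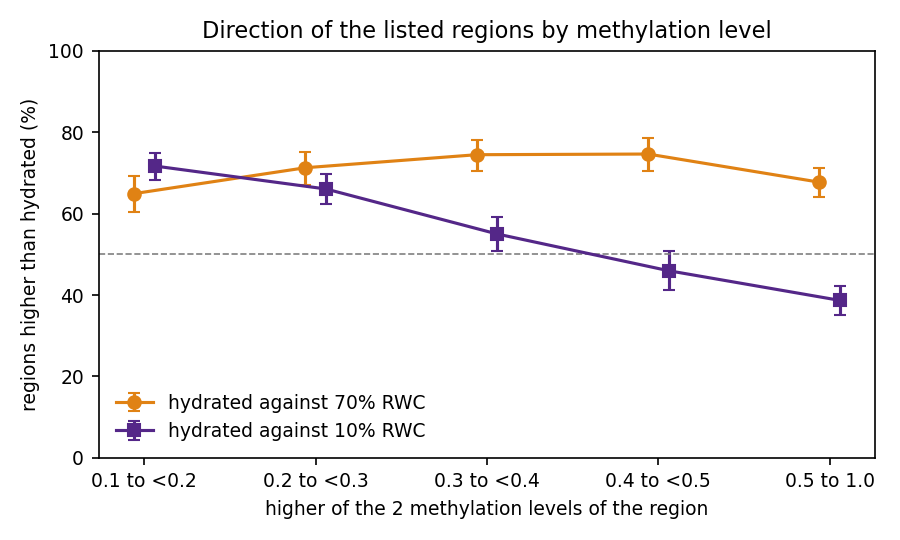
Share of listed regions with a higher level than in the hydrated leaf (percent, with exact 95% binomial intervals), by the higher of the 2 methylation levels of the region (fraction), for 70% RWC (circles) and 10% RWC (squares). The 10% RWC share runs from 71.7% in the lowest group to 38.7% in the highest, and the 70% RWC share stays between 64.9% and 74.6%.

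Listed regions were spread over gene bodies and flanks in like proportions in both comparisons, but their directions were not. Gene bodies carried the region for 44.3% of listed genes at 70% RWC and 44.2% at 10% RWC. The remainder lay upstream (26.6% and 27.3%) or downstream (29.1% and 28.5%). At 70% RWC the increased share was much the same in all 3 places, 71.3% upstream, 71.0% in bodies and 69.3% downstream. At 10% RWC it was 61.5% in gene bodies (995 of 1618), 50.1% upstream (500 of 999) and 52.3% downstream (546 of 1043). The odds of an increase in bodies against flanks were 1.52 at 10% RWC (1.33 to 1.74; two-sided Fisher exact test, Benjamini-Hochberg adjusted p 1.1e-09) and 1.04 at 70% RWC (0.89 to 1.21, adjusted p 0.666). Among differences of at least 0.3 the 70% RWC odds ratio was 1.51 (1.09 to 2.12), so the bodies of that list also leaned to increases among its larger changes. Over the 4313 genes in 1 list only, the 10% RWC odds ratio was 1.44 times the 70% RWC one (1.12 to 1.86, p 0.00527 for the interaction).

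**Figure D2:**
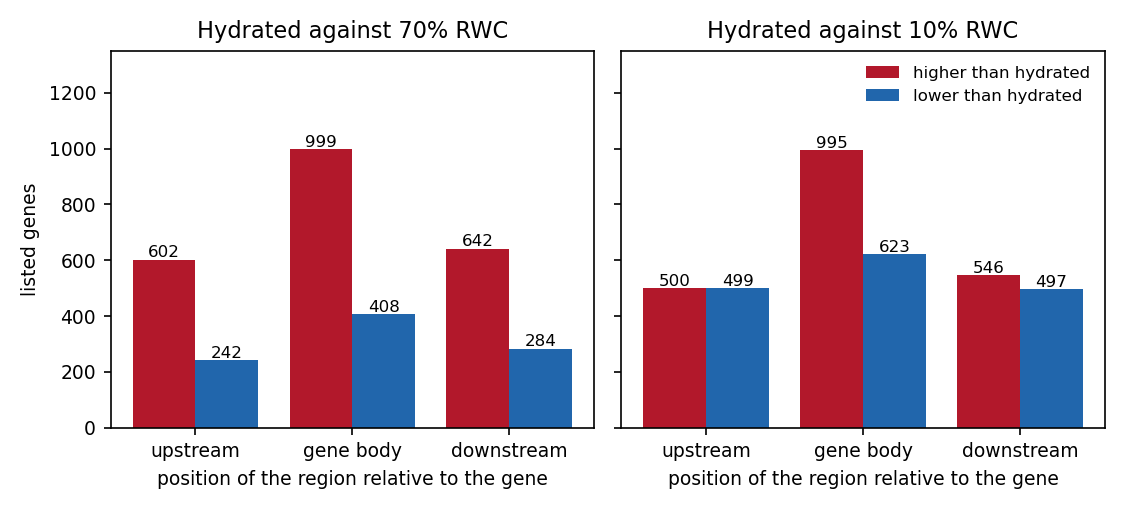
Number of listed genes whose region was upstream, in the gene body or downstream, split by a higher (red) or lower (blue) level than in the hydrated leaf, for 70% RWC (left) and 10% RWC (right). At 10% RWC the flanks are near balance, with 500 and 499 genes upstream, and gene bodies have 995 higher against 623 lower.

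Some of the regions listed at 70% RWC were met again at 10% RWC, nearly always with the same direction. There were 712 overlaps of at least 1 bp, which involved 26.4% of the 70% RWC regions and 23.0% of the 10% RWC regions. In 672 of them (94.4%, 92.4 to 96.0) the direction was the same, higher in 480 and lower in 192. Both comparisons use the same hydrated library, so unchanged libraries also give this kind of match. In a simulation of unchanged dehydrated libraries, 91.3%, 98.7% and 99.6% of regions listed in both had the same direction with 20, 50 and 100 assumed calls per region, where the true number is unknown. Simulated regions had the same boundaries in both comparisons, and the observed overlaps with identical boundaries all matched (114 of 114, 96.8% to 100%). The simulated values with 50 and 100 calls lie within that interval, so the match alone does not tell changed from unchanged libraries. Of the simulated matches, 59.3%, 60.6% and 63.7% were higher, against 480 of 672 observed and 88 of 114 with identical boundaries. That difference was not tested. By gene, 1262 of 5575 were in both lists, and 82.1% of these had the same direction. Independent lists drawn from the 18649 genes numbered on the listed scaffolds would share 624 genes, 245 with a higher and 81.1 with a lower level in both, against 751 and 285 observed. The number of genes that could have been listed is unknown. Totals of 9214 genes would give the observed overlap by chance, 6096 the overlap of higher levels and 5306 that of lower levels, and part of the excess may come from the shared hydrated library. Of the 432 shared genes listed for a different region in each comparison, 58.3% had the same direction, where 54.1% follows from the direction shares alone.

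Among the regions that matched in direction, the 5 largest shared changes were gains at genes without a description. They were downstream of Bhs9669_003V1.1, in the bodies of Bhs188977_001V1.1 (0.23 and 1 at 70% RWC, 0.26 and 0.98 at 10% RWC), Bhs5319_002V1.1 (0.20 and 1, 0.29 and 1) and Bhs14970_001V1.1 (0.13 and 0.80, 0.22 and 0.92), and upstream of Bhs3527_001V1.1 (0.31 and 0.96, 0.18 and 1). Genes of known function in both lists included the chaperonin GroEL gene Bhs704_044V1.1, whose upstream level was 0.08 and 0.50 in the first comparison and 0.07 and 0.55 in the second. Upstream of the pectate lyase gene Bhs4381_002V1.1, a pectin-degrading enzyme, the level was 0.56 in the hydrated leaf, 0.17 at 70% RWC and 0.10 at 10% RWC. The peroxidase gene Bhs12_006V1.1 had 0.06, 0.43 and 0.40 upstream. Opposite directions were listed in 40 overlaps, 31 of them higher at 70% RWC and lower at 10% RWC. These opposite overlaps often gave the hydrated library itself different levels: downstream of Bhs2152_012V1.1, a polyneuridine-aldehyde esterase, nearly the same stretch had a hydrated level of 0.26 in one table and 0.68 in the other.

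Regions in both lists give a level at all 3 water contents, but only those with identical boundaries give it for the same stretch. Over the 672 overlaps of the same direction, the hydrated levels of the 2 comparisons differed by a median of 0.02 (quartiles 0 and 0.06). Regions in both lists passed the selection in both comparisons, so they cannot show how often an early difference was lost. The 10% RWC levels of the other 70% RWC regions are not given. Within this selected set, gains were slightly smaller in the desiccated leaf. Overlap by overlap, the median change in the size of a gain, 10% minus 70% RWC, was -0.02. For losses this median change was 0 (quartiles -0.0225 and 0.0225). Of the 480 overlaps with a higher level in both comparisons, 301 (62.7%, 58.2 to 67.0) lay closer to the hydrated level at 10% RWC than at 70% RWC, 153 lay further away and 26 were level. Their median differences were 0.22 at 70% RWC and 0.20 at 10% RWC. Of the 192 with a lower level in both, 93 were closer (48.4%, 41.2 to 55.7), 77 further and 22 level, with median absolute differences of 0.25 at 70% RWC and 0.23 at 10% RWC. Most of these moves were small: 12.3% of the gains were closer by at least 0.1 and 3.75% further by as much, and for the losses both shares were 4.69%. At the 114 regions with identical boundaries in both lists, 88 were higher and 26 lower in both, and the hydrated level was the same in 113. Of these 88 gains, 56 (63.6%, 52.7 to 73.6) lay closer to the hydrated level at 10% RWC and 28 further, with a median change of -0.02. Of the 26 losses, 11 lay closer and 11 further.

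Genes were also read in 10 functional lists fixed before the data were examined, drawn from what is known of drying leaves and of plant DNA methylation. No list leaned to one direction beyond the other listed genes after correction over 16 two-sided Fisher exact tests (smallest Benjamini-Hochberg adjusted p 0.234). Only very strong leans were tried on simulated data, so moderate leans could have been missed. Photosynthesis and chlorophyll-binding genes leaned most to gains. Their level was higher for 22 of 25 genes at 70% RWC (p 0.0751, adjusted 0.401) and for 17 of 21 at 10% RWC (p 0.0255, adjusted 0.234; two-sided Fisher exact tests). The comparisons are not independent, since they share the hydrated library and 15 of these genes. In 14 members of each list membership rests on a Gene Ontology term alone; by description, 10 of 11 and 6 of 7 genes were higher (adjusted p 0.562 for both). Genes of the abscisic acid list were lower for 13 of 18 at 10% RWC (two-sided Fisher exact test, p 0.0292, adjusted 0.234) and higher for 5 of 7 at 70% RWC. This list mixes genes of synthesis, signalling and breakdown of the hormone. For 6 of the 18 and 2 of the 7, membership rests on a Gene Ontology term alone. By description alone 10 of 12 were lower at 10% RWC (two-sided Fisher exact test, p 0.00761, adjusted 0.122). The direction tests are not matched on level. Among 10000 random lists matched on mean level, the median difference of the abscisic acid list lay at percentile 7.87 at 10% RWC. That of the photosynthesis list lay at percentile 78.6 at 70% RWC and 94.2 at 10% RWC. Cell wall genes were higher for 20 of 28 at 70% RWC and for 10 of 24 at 10% RWC. Their median difference at 10% RWC was -0.205, at the 0.455 percentile of 10000 random lists matched on mean level. This was the most extreme of the 16 percentiles, and the matching direction test had an adjusted p of 0.575.

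Genes of the antioxidant list were higher for 22 of 27 at 70% RWC, with a median at percentile 96.6, and for 18 of 29 at 10% RWC, at percentile 50.3. This list was drawn by the keywords superoxide dismutase, catalase, peroxidase, glutathione and thioredoxin. It is wider than genes that remove reactive oxygen, and includes glutathione S-transferases. Chaperone genes were higher for 22 of 35 and 21 of 30, transcription factor genes for 18 of 24 and 14 of 32, and genes of the sucrose, trehalose and raffinose list for 6 of 7 and 3 of 8. By description alone, 3 of 3 and 1 of 5 genes of this sugar list were higher. The higher gene at 10% RWC was the trehalose-phosphate synthase gene Bhs4909_003V1.1. Among genes of the DNA methylation machinery, 4 of 6 and 5 of 8 were higher. One of them, Bhs208_029V1.1, encodes an argonaute, a protein that loads small RNAs, and had an upstream level of 0.13 in the hydrated leaf and 0.53 at 70% RWC. No listed gene was described as a late embryogenesis abundant protein, a dehydrin or a transposon. Only 49.2% and 48.8% of listed genes carried a description, so these absences cover the described genes alone.

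**Figure D3:**
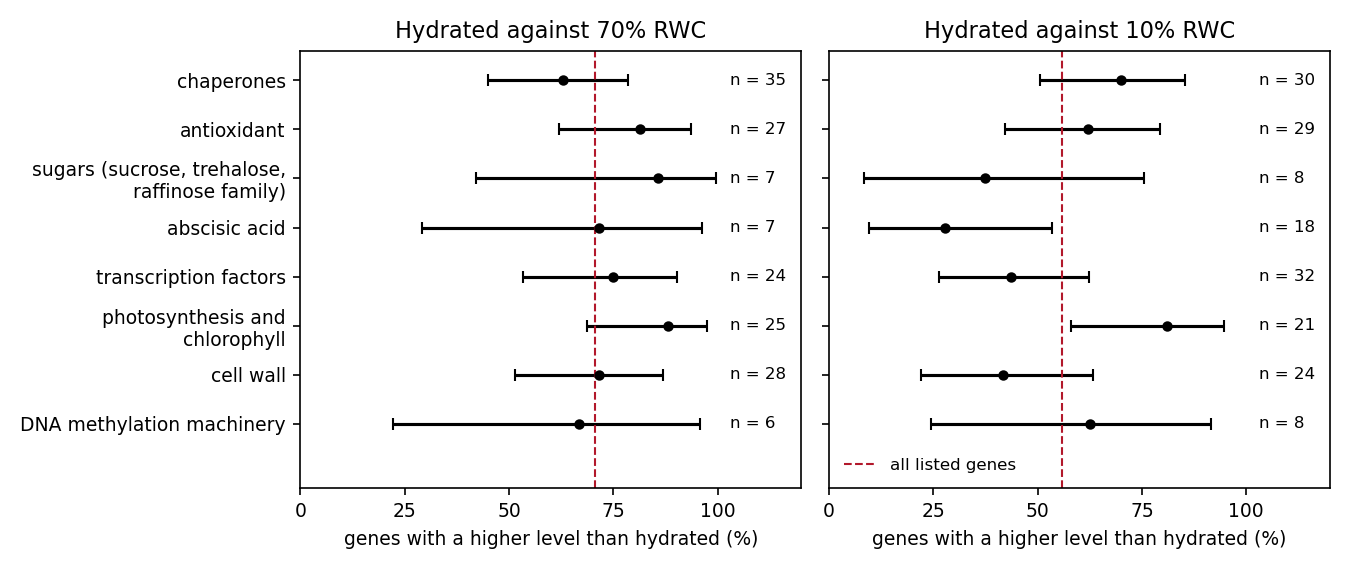
Percent of genes in each functional list with a higher level than in the hydrated leaf (points, with exact 95% binomial intervals), for 70% RWC (left) and 10% RWC (right); n is the number of listed genes, and the dashed line is the share over all listed genes (70.6% and 55.8%). Photosynthesis genes lie above the line in both, at 88.0% and 81.0%, and abscisic acid genes lie lowest at 10% RWC, at 27.8%.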

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

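The tests of conversion, of a noisier hydrated library and of the opposite overlaps, and the noise simulation, were chosen after the results were seen; the length, level and single-gene tests were set out before their results were seen.

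The increased share was 14.5 percentage points higher at 70% RWC than at 10% RWC, and its fall from weakly to strongly methylated regions was 35.8 points steeper at 10% RWC (28.5 to 43.1). At high depth, uniform incomplete conversion in the 70% RWC library would leave hardly any region near 0. A level of 0.02 or less was listed there for 128 of its regions (4.76%, 3.98 to 5.63). At low depth a region can read near 0 even with incomplete conversion, and depth is unknown, so this test cannot decide about conversion. A noisier hydrated library would give the 70% RWC list a similar fall, which was -2.81 points (-8.27 to 2.65). Noise that differs between the dehydrated libraries stays open: with region length standing in for depth, the share difference was 14.6 points among the longest 25% of regions and 12.1 among the shortest, a gap of 2.45 (-4.50 to 9.40), and the fall at 10% RWC was 33.4 points larger among the longest regions (19.4 to 47.3). That second gap goes against noise as set out beforehand, but the expectation was wrong: in simulated unchanged libraries with 10 assumed calls per region of median length, noise alone gave falls of 14.1 and 34.8 points with a dehydrated library 2 and 4 times deeper, 28.1 and 23.3 points larger among the longest regions, and with 20 calls falls of 20.7 and 34.8 points with gaps of -3.52 and -0.661, so noise reached the observed 33.0 points only at the larger depth ratio. Desiccation is the biological explanation the design offers; a mix of sequence contexts that differ in level could also produce the fall, and neither was tested.

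Gene bodies leaned to increases more than flanks did at 10% RWC, and over the 4313 genes in 1 list only the odds ratio there was 1.44 times that at 70% RWC (1.12 to 1.86). The contrast between the lists was smaller in other settings, 1.32 against 1.06 (0.91 to 1.24) within bins of level and 1.82 against 1.51 at differences of at least 0.3, with overlapping intervals in both, and was not tested there. A surplus of weakly methylated regions in bodies lowers the odds ratio of 1.52 only to 1.32 (1.15 to 1.51) within bins of level, so it does not account for the whole. Flanking regions counted for more than 1 gene do not account for it either, since regions listed for a single gene gave 1.59 (1.36 to 1.87). Gene bodies of plants are often methylated in CG alone, so a change that differs by context may lie behind the contrast; context and the effect of desiccation were not tested.

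Overlapping regions with opposite directions were singled out because the dehydrated leaves lay on either side of the hydrated one, a difference that was not tested. The 5 largest had differences of 0.31 and -0.35 downstream of Bhs2152_012V1.1, 0.41 and -0.31 upstream of Bhs63_011V1.1, 0.30 and -0.39 upstream of Bhs6326_002V1.1, 0.32 and -0.30 upstream of Bhs2589_002V1.1, described as a phospholipid-transporting ATPase, and 0.28 and -0.28 in the body of Bhs2720_005V1.1, at 70% and 10% RWC in turn. The regions of Bhs63_011V1.1, Bhs2720_005V1.1 and Bhs2589_002V1.1 share only 1, 23 and 30 bp, so their differences belong to neighbouring stretches. Opposite directions were concentrated where the regions shared little sequence, 27 of 135 overlaps below a reciprocal 50% against 13 of 577 above it (odds ratio 10.8, 5.19 to 23.5), so many may describe neighbouring stretches. For the 13 close overlaps, the 2 tables may average different cytosines: their hydrated levels differed by a median of 0.07 (0.04 to 0.12), against 0.02 over the 564 close overlaps of the same direction, and at Bhs6326_002V1.1 they were 0.11 and 0.67 over nearly the same 356 bp. At Bhs2152_012V1.1 they were 0.26 and 0.68, also over nearly the same stretch. The same library cannot give both levels from the same calls, so neither of these pairs can show a reversal past the hydrated level. For the other close overlaps, which are few, an average over different cytosines and a real reversal during drying cannot be told apart.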

How the results depend on the processing

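Counts by gene, regions outside the other list, single-gene regions, bins of level and lists by description were chosen after the data had been seen; the other settings were planned. Under the alternatives 49 values held, among them the side of each of the 16 functional lists by description, 28 moved, 2 reversed and 1 passed its threshold, and the cause was not tested unless the setting itself removes regions.

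A minimum difference changed the 10% RWC majority: the increased share was 45.9% (750 higher, 884 lower) at 0.2, 40.9% (299 and 432) at 0.3 and 51.8% (43 and 40) at 0.5. The 70% RWC majority held: 1118 and 449 at 0.2, 67.1% (469 and 230) at 0.3, and 64.4% (65 and 36) at 0.5. With 1 region per scaffold there were 954 and 402 at 70% RWC, and 820 and 695 (54.1%) at 10% RWC. Outside the other list the 10% RWC share was 52.1%. Overlaps with the same direction were 97.7% at a reciprocal 50%, 100% of 114 with identical boundaries, and 96.8% of 124 with differences of at least 0.3 in both. Moves of at least 0.1 towards the hydrated level were 12.3% of gains and 4.69% of losses. Gene bodies against flanks at 70% RWC gave an odds ratio of 1.51 at differences of at least 0.3.

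Thresholds on p, on cytosine number or on coverage and a split by context could not be run, because the tables hold none of these, and each gene occurs once, so counting genes once changes no functional list. No paired analysis was possible because each condition has 1 library. With unknown depth, noise in single regions cannot be bounded.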

Other observations

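Both tests in this part were chosen after the data had been seen.

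The families here are genes with the same KEGG description, and a gene need not have the function of the protein its description names. Among families with many listed members, genes described as structure-specific endonuclease subunit SLX1, a nuclease that resolves branched DNA, were the most numerous. Their level was higher for 28 of 44 at 70% RWC and 27 of 39 at 10% RWC. Of all listed genes, 70.6% and 55.8% were higher. Genes described as exopolyphosphatase were higher for 11 of 12 and 14 of 17. Receptor kinases went both ways at 10% RWC: genes described as brassinosteroid insensitive 1, the brassinosteroid receptor, were higher for 13 of 20 at 70% RWC and 11 of 18 at 10% RWC, and those described as its partner BAK1 for 4 of 9 and 4 of 11. Genes described as RPM1, an intracellular receptor of pathogen effectors, were higher for 7 of 12 and 8 of 18, and those described as the kinase PBS1 for 11 of 14 and 12 of 23. Peptide and histidine transporter genes of solute carrier family 15 were higher for 8 of 9 at 70% RWC and 8 of 16 at 10% RWC. Genes described as the receptor kinase FLS2 were higher for 9 of 15 and 11 of 20, those of the nucleobase:cation symporter family for 8 of 13 and 9 of 13, and those described as interleukin-1 receptor-associated kinase 4 for 7 of 8 and 9 of 20. These families are a choice made after the data had been seen among those with at least 8 listed genes, and no test was made on them.

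If changes spread along scaffolds, neighbouring regions would share their direction more often than shuffled ones. At 10% RWC 51.6% of 1578 neighbouring pairs shared a direction against 50.7% after shuffling (percentile 78.1 of 10000 shufflings), and at 70% RWC 58.9% of 1334 pairs against 58.3% (percentile 68.8). A shared direction of neighbours was not detectable here.

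No Gene Ontology term leaned to one direction after correction. Over 136 tests of terms with at least 20 genes, 9 had an unadjusted p under 0.05 and the smallest adjusted p was 0.067, for transferase activity at 70% RWC, whose genes were higher for 9 of 25 (two-sided Fisher exact test). Genes of cofactor binding were higher for 10 of 32 at 10% RWC (adjusted p 0.447).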
